A study of Homo sapiens with 4 samples.

How the data were processed

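Total RNA of 4 cultures of MCF10A cells, a non-tumorigenic human mammary epithelial cell line, was measured on Affymetrix arrays, with 1 array for each of vector, YAP-WT, YAP-S94A and YAP-W1W2. The cells had been infected with a retrovirus made from the empty pQCXIH vector or from the same vector carrying a form of YAP, and grew in medium with horse serum, epidermal growth factor, hydrocortisone, cholera toxin and insulin. The deposited values are array intensities on a linear scale, and the software named in the submitters' processing notes is GCOS, the Affymetrix operating software; its version and its scaling target are not given in the sources used here. Per the labels' protocols, RNA was extracted with Trizol and labelled with biotin. No genome build is named for the arrays, so no coordinates are given. No detection calls were used here.

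The value table held 54675 probe sets, of which 62 were Affymetrix controls and were kept apart. Gene names came from the platform's annotation table: 41097 probe sets had 1 gene symbol, 1801 had several and 11777 had none. Of the probe sets with 1 symbol, 41043 had an Entrez identifier in the RefSeq gene table of assembly GRCh38.p14, which was used for names only, and 0 symbols needed updating. No gene was named from a probe set with several symbols.

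The 2% trimmed means of the 4 arrays ran from 458.4 to 503.3, a ratio of 1.098. This lay within the 10% allowed before the data were examined, so the values were used as deposited. Intensities below 72.9, the 40th percentile over all arrays, were set to that floor, and log2 was taken. A fold with 1 side at the floor is a lower bound and is written as at least that fold. A fold with 1 side just above the floor is given as measured, though it is close to such a bound. Each gene was represented by the probe set with the highest mean signal among those with 1 symbol, which gave 19775 genes. The 12759 genes with a mean signal of at least 113.6, the median over probe sets, are called measured. The number of arrays limits the precision: with 1 array per group there is no replicate check, so no test, standard error or p-value across genes was computed, and genes were counted by a fixed size of change of 2-fold.

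Genes named in the text followed a rule fixed before the data were examined, as were the gene lists, groups, comparisons and main settings. For each comparison with vector the 12 highest and 12 lowest measured genes with both arrays above the floor could be named, and the 8 highest and 8 lowest for each mutant against YAP-WT. YAP1 and every measured member of the YAP target list could be named too, and in the other lists up to 4 members changed at least 2-fold, or the 2 largest changes where none was. Genes named outside the rule are marked where they appear. Where a gene had several measured probe sets, the range of their folds was looked up, and opposite directions are stated.

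There were 29 gene lists, for YAP targets, Hippo pathway components, epithelial junctions, mesenchymal genes, DNA replication, mitosis, EGF family ligands, keratinocyte differentiation, extracellular matrix, actin cytoskeleton and SRF, interferon response, inflammatory cytokines and NF-kB, cholesterol synthesis, hypoxia and glycolysis, unfolded protein and amino acid response, p53 targets, apoptosis regulators, the TGF-beta and BMP, Wnt and Notch pathways, immediate early genes, basal and luminal mammary cells, stem-like cells, fibroblasts, immune cells, endothelial cells, cytosolic ribosomal proteins and the mitochondrial respiratory chain. A list is described by the median log2 fold of its measured members and by how many of 10000 random lists, of the same size and matched on mean signal in 10 bins, lay below that median. This describes these arrays and is no test of the conditions. In each comparison more of the 29 lists lay outside the central 95% of random lists than the 1.5 expected by chance. For YAP-WT against vector, 9 lay above and 8 below, and for YAP-W1W2 against YAP-S94A, 9 above and 7 below. A place outside the random lists is therefore common here and does not by itself set a list apart. A gene at least 2-fold changed in YAP-WT was called retained in a mutant if it was at least 2-fold changed the same way there, and lost if its log2 change was under 0.5 in that direction. Shares carry 95% Wilson intervals, which treat genes as independent and leave out array error.

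The comparisons with vector share 1 array, so the correlation between them was simulated with no effect in 100 draws. The procedure was tested on simulated arrays for YAP-WT against vector with 12766 genes. Of 190 measured genes changed 4-fold, 178 (93.7%) passed the 2-fold rule. Among the unchanged genes 1424 (11.32%) passed it too, with noise set as large as the whole difference between the YAP-WT and YAP-W1W2 arrays. This overstates the noise of that pair where those forms truly differ. Whether it bounds the noise of the vector or YAP-S94A array cannot be told with 1 array each. The alternatives were median centring, quantile and cyclic loess normalization, a floor at the 20th percentile, no floor with log2 of the value plus 16, no filter and a filter at the 70th percentile of signal, the mean over a gene's probe sets, probe sets without the _s_at or _x_at suffix only, and a 3-fold threshold. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1.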

Results

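Gene expression was profiled in MCF10A human mammary epithelial cells that carried the empty retroviral vector, wild-type YAP (YAP-WT), YAP-S94A or YAP-W1W2. YAP is the transcriptional coactivator held in check by the Hippo pathway. The S94A change lies in the part of YAP that binds the TEAD transcription factors, and in W1W2 both WW domains, which bind proline-rich partners, are mutated. There was 1 array per group and no replicate, so each difference is between 2 arrays and has no replicate check. Over the 54613 probe sets that are not controls, the median intensity was 116.2 in vector, 112.3 in YAP-WT, 113.5 in YAP-S94A and 116.1 in YAP-W1W2. Of 12759 measured genes, 1.615% to 2.508% lay at or below the floor on an array.

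The 3 probe sets for YAP1 differed from vector by log2 values of −0.24 to 0.60 over the 3 YAP forms, and in YAP-WT by at most 0.13 upwards. Whether these probe sets lie within the constructs is not known, so these values cannot tell a construct they do not see from little added transcript. Across genes, the vector array correlated least with the others, with Pearson's r of 0.9252 with YAP-WT, 0.9118 with YAP-S94A and 0.8883 with YAP-W1W2. Among the YAP arrays r was 0.9318 for YAP-WT with YAP-S94A, 0.9467 for YAP-WT with YAP-W1W2 and 0.9419 for the mutants. Genes are not independent replicates. The bacterial hybridization controls differed from vector, in YAP-WT, YAP-S94A and YAP-W1W2 in turn, by log2 values of −0.52, −0.80 and −1.16 for bioB, −0.34, −0.73 and −1.01 for bioC, −0.30, −0.63 and −0.75 for bioD, and 0.02, −0.04 and −0.22 for cre. The median gene was shifted from vector by 0.14 (log2) in YAP-WT, 0.14 in YAP-S94A and 0.10 in YAP-W1W2, and list medians are also given relative to it where stated.

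YAP-WT was compared with vector to ask which transcripts differ when YAP is expressed. Genes of cell division, known YAP targets and extracellular matrix genes were higher, and genes of keratinocyte differentiation and inflammatory cytokines were lower. The largest difference among genes above the floor on both arrays was OLR1, an oxidized LDL receptor, at 30.1-fold higher, followed by the integrin subunit ITGB2 (23.7-fold), CCN2 (17.1-fold), the metalloprotease ADAMTS1 (15.7-fold), SFTA1P (13.5-fold), the potassium channel KCNT2 (12.2-fold), RIMS2 (11.8-fold), the guidance ligand SLIT2 (11.4-fold), ZBED2 (10.8-fold), ZNF385B (10.5-fold), FRY (10.3-fold) and the transglutaminase TGM2 (10.2-fold). SFTA1P rested on 1 probe set with an intensity of 79.3 in vector, near the floor. The placental alkaline phosphatase ALPP, named after its values were seen, was at or below the floor in vector and at least 27.8-fold higher in YAP-WT. In all, 1162 genes were at least 2-fold higher and 631 at least 2-fold lower, so 64.8% of the changed genes were higher. After median centring the counts were 878 and 874, with 50.1% higher. The 1793 changed genes were 14.1% of those measured; in simulated arrays 11.32% of unchanged genes passed 2-fold, with noise as large as the whole difference between the YAP-WT and YAP-W1W2 arrays, so single genes near 2-fold are not resolved from noise.

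Of 27 measured YAP target genes, 16 were at least 2-fold higher in YAP-WT than in vector and 0 lower. This list drew in part on YAP overexpression in MCF10A cells and is not independent evidence of its direction. Its median log2 fold was 1.29, or 1.16 relative to the median gene, above all 10000 random lists. The matricellular genes CCN2 and CCN1 were 17.1-fold and 3.77-fold higher, the IGF-binding protein IGFBP3 9.40-fold, the neurotrophin BDNF 6.18-fold, the activin subunit INHBA 5.17-fold, the ecto-nucleotidase NT5E 5.11-fold and the receptor tyrosine kinase AXL 3.85-fold. ANKRD1 was at least 2.62-fold higher. Of 32 measured extracellular matrix genes 17 were higher and 2 lower, with a median of 1.32, above all random lists. Among them, the collagen COL8A1 was 10.0-fold higher, the thrombospondin THBS1 9.24-fold, and the fibulin FBLN5 at least 11.5-fold. CCN1 and CCN2 stand in both lists.

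Cell division genes were higher. In the mitosis list, 34 of 35 measured genes were at least 2-fold higher in YAP-WT than in vector, with a median log2 fold of 1.88. The anaphase activator CDC20 was 6.02-fold higher, the survivin gene BIRC5 5.69-fold, the kinetochore gene NUF2 5.70-fold and the cyclin CCNA2 5.06-fold. In the DNA replication list 22 of 31 were higher, with a median of 1.36. The helicase cofactor CDC45 was 6.69-fold higher and MCM10 4.99-fold, and E2F1 was at least 7.21-fold higher. GINS2 was 5.04-fold higher by its brightest probe set, while another of its probe sets went the other way. Both medians lay above all 10000 random lists. On the same arrays the actin controls were higher than in vector by 0.43 (log2) and GAPDH by 0.22.

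The genes lower in YAP-WT than in vector were led by the calcium-binding protein CALB1 (11.6-fold lower), the basal keratin KRT15 (11.4-fold), the aldehyde dehydrogenase ALDH3A1 (9.95-fold), AZGP1 (9.60-fold), the epithelial transcription factor EHF (9.02-fold), the kallikrein KLK7 (8.01-fold) and the pyruvate dehydrogenase kinase PDK4 (7.33-fold). SPRR1B, a cornified envelope precursor, was 6.84-fold lower, PNRC1 6.72-fold, SERPINA3 6.62-fold and PNLIPRP3 6.60-fold. ZNF335 was 6.97-fold lower by 1 probe set, and its other probe set was higher. In the keratinocyte differentiation list 19 of 28 measured genes were at least 2-fold lower and 2 higher, with a median log2 fold of −1.81, below all random lists. S100A7 was at least 21.5-fold lower, SPRR3 at least 14.9-fold and CRABP2 at least 9.81-fold. In the list of inflammatory cytokines and NF-kB genes 12 of 20 were lower and 2 higher, with a median of −1.34, below all random lists. The neutrophil chemokines CXCL1 and CXCL2 were 6.13-fold and 5.51-fold lower, whereas PTGS2, which encodes cyclooxygenase-2, was 6.49-fold higher. Without the filter on dim genes the median of this list was −0.45. Epithelial junction genes had a median of −0.39, with 6 of 24 lower, among them the desmoglein DSG3 (6.41-fold), the splicing regulator ESRP1 (3.61-fold) and the claudins CLDN7 (3.05-fold) and CLDN4 (at least 3.58-fold), and 1 higher.

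**Figure D1:**
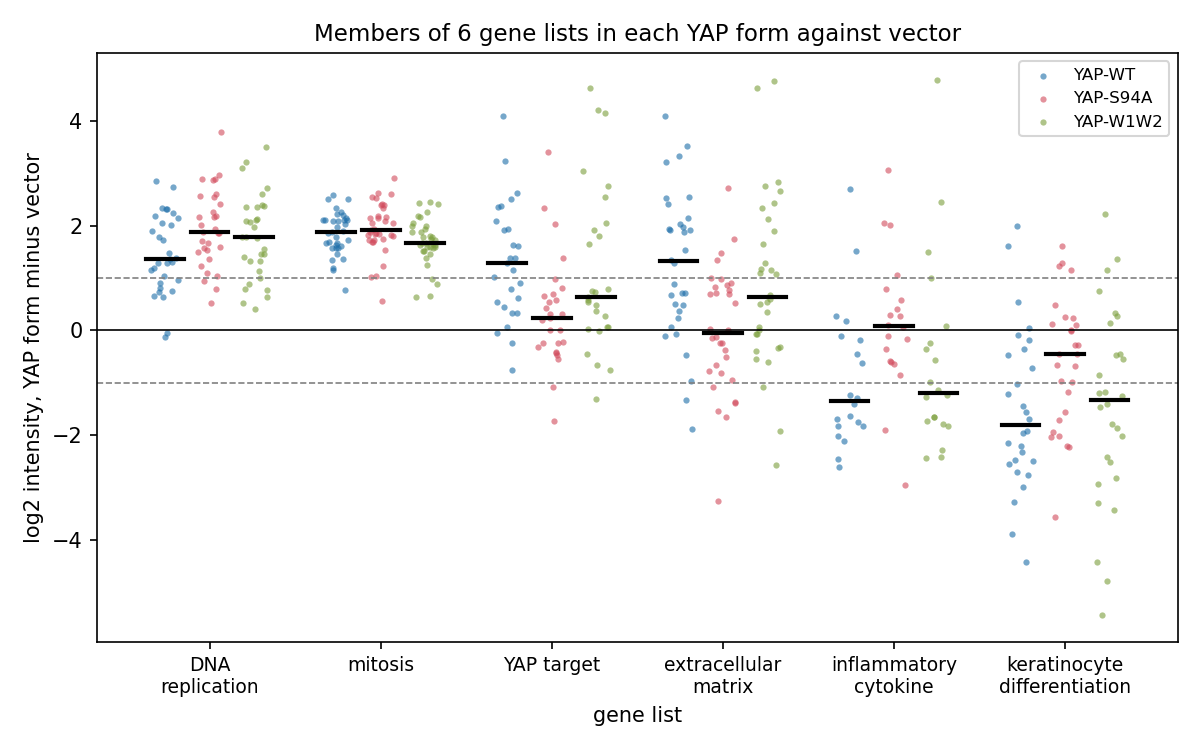
Each point is a measured member of a gene list, and the vertical axis is its log2 intensity in a YAP form minus that in vector, with 1 array each; black bars are list medians and dashed lines mark 2-fold. The mitosis medians lie at 1.88, 1.91 and 1.67 in YAP-WT, YAP-S94A and YAP-W1W2, while the YAP target medians lie at 1.29, 0.24 and 0.63.

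YAP-S94A was compared with vector to ask which differences appear with a YAP defective in TEAD binding. Cell division genes were again higher, and YAP targets as a list were not. In the mitosis list 34 of 35 genes were at least 2-fold higher, with a median log2 fold of 1.91, and in the DNA replication list 28 of 31, with a median of 1.87; both lay above all 10000 random lists. CDC45 was the highest named gene at 13.9-fold, and the polo-like kinase PLK1 was 7.52-fold higher. The other leading genes were the uridine phosphorylase UPP1 (12.3-fold), the lipase inhibitor ANGPTL4 (11.4-fold), the ERK phosphatase DUSP6 (11.1-fold), the xanthine dehydrogenase XDH (10.8-fold), NT5E (10.6-fold), RMI2 (10.4-fold), AMIGO2 (10.0-fold), AKAP12 (9.47-fold), the centromere chaperone HJURP (9.14-fold) and DEPDC1B (8.93-fold). HMGA2 was 9.63-fold higher by its brightest probe set and 0.16 (log2) by another.

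Of 27 YAP target genes, 4 were at least 2-fold higher in YAP-S94A than in vector and 2 lower, with a median log2 fold of 0.24, above 6264 of 10000 random lists. The higher ones were NT5E, BIRC5 (5.04-fold), the coagulation initiator F3 (4.09-fold) and FJX1 (2.62-fold). CCN2 stood at a log2 fold of 0.98, AXL at 0.42, INHBA at 0.32, and CCN1 and IGFBP3 at −0.25 each; probe sets of CCN1 and IGFBP3 went in both directions. Extracellular matrix genes had a median of −0.06, with 5 of 32 higher and 6 lower; the median was 0.01 with the mean over probe sets. Tenascin C (TNC) was 6.58-fold higher and periostin (POSTN) 9.59-fold lower. EGF family ligands were led by HBEGF, 7.61-fold higher, and 3 of 5 passed 2-fold.

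The genes lower in YAP-S94A than in vector were led by the proteoglycan decorin (DCN, 32.4-fold lower), the cytochrome CYP1B1 (29.8-fold), the selenium carrier SELENOP (15.3-fold), GAS1 (14.9-fold), KLHL24 (13.8-fold), DSEL (13.2-fold), PNRC1 (12.7-fold), EHF (12.4-fold), the calprotectin subunit S100A8 (11.9-fold), the monoamine oxidase MAOA (11.1-fold), WNT5A (10.3-fold) and the aquaporin AQP3 (9.91-fold). PDK4 was at least 25.8-fold lower and the muscle-atrophy ubiquitin ligase FBXO32 at least 33.2-fold, both named after their values were seen. Keratinocyte differentiation genes had a median log2 fold of −0.46, below all random lists, with 9 of 28 lower and 4 higher. Inflammatory cytokine genes had a median of 0.08, which was −0.07 after median centring, with 4 of 20 higher and 2 lower; the neutrophil chemokine CXCL8 was 8.39-fold higher and the superoxide dismutase SOD2 7.71-fold lower. Altogether 1312 genes were at least 2-fold higher and 833 lower, so 61.2% were higher. After median centring the counts were 986 and 1097, with 47.3% higher. The actin controls were higher than in vector by 0.68 (log2).

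YAP-W1W2 was compared with vector to ask which differences appear without intact WW domains. It had 1460 genes at least 2-fold higher and 1072 lower, with 57.7% higher. Of the YAP arrays, this 1 had the most changed genes, and its bacterial hybridization controls also differed most from vector. Whether these are linked was not tested. The leading genes were SFTA1P (31.7-fold higher), PTGS2 (27.6-fold), DAW1 (25.6-fold), CCN2 (a log2 fold of 4.64), the cystatin CST6 (22.5-fold), NT5E (18.6-fold), IGFBP3 (17.7-fold), MTARC1 (15.7-fold), RIMS2 (13.4-fold), OLR1 (13.3-fold), CAPN6 (12.8-fold) and ZBED2 (a log2 fold of 3.58). The vector intensity of SFTA1P was 79.3, near the floor. The neuron navigator gene NAV3, named after its values were seen, was at least 42.7-fold higher. Of 27 YAP target genes 10 were higher and 1 lower, with a median log2 fold of 0.63, above 9996 of 10000 random lists. BDNF was 8.24-fold higher, INHBA 6.78-fold and CCN1 3.14-fold, while AXL stood at −0.46 (log2), with probe sets in both directions. Extracellular matrix genes had a median of 0.63, above all random lists, with 15 of 32 higher and 3 lower. In the mitosis list 31 of 35 were higher (median 1.67) and in the DNA replication list 24 of 31 (median 1.78), again above all random lists. CDC6, which loads the replicative helicase, was 9.29-fold higher and the ribonucleotide reductase subunit RRM2 8.56-fold.

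Genes lower in YAP-W1W2 than in vector were led by the chloride channel regulator CLCA2 (48.8-fold lower), S100A8 (43.3-fold), DCN (37.6-fold), SPRR1B (27.9-fold), CYP1B1 (27.5-fold), the serpin SERPINB13 (27.0-fold), ALDH3A1 (26.1-fold), EHF (22.3-fold), MATR3 (15.7-fold), TMT1A (15.0-fold), AZGP1 (14.6-fold) and ELL3 (a log2 fold of −3.81). Of these 12 genes, 5 rested on 1 measured probe set. Among them, ALDH3A1, MATR3 and AZGP1 had intensities in YAP-W1W2 of 75.1, 86.7 and 91.3, near the floor. EHF, with several probe sets, stood at 95.6. Keratinocyte differentiation genes had a median log2 fold of −1.33, with 17 of 28 lower and 3 higher. Inflammatory cytokine genes had a median of −1.19, with 11 of 20 lower and 4 higher; CXCL1 was 5.38-fold lower and the chemokine CCL20 5.49-fold higher. Both medians lay below all random lists, and that of the cytokine list was −0.39 without the filter on dim genes and −0.40 with probe sets lacking the _s_at or _x_at suffix only. The actin controls were higher than in vector by 0.80 (log2).

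**Figure D2:**
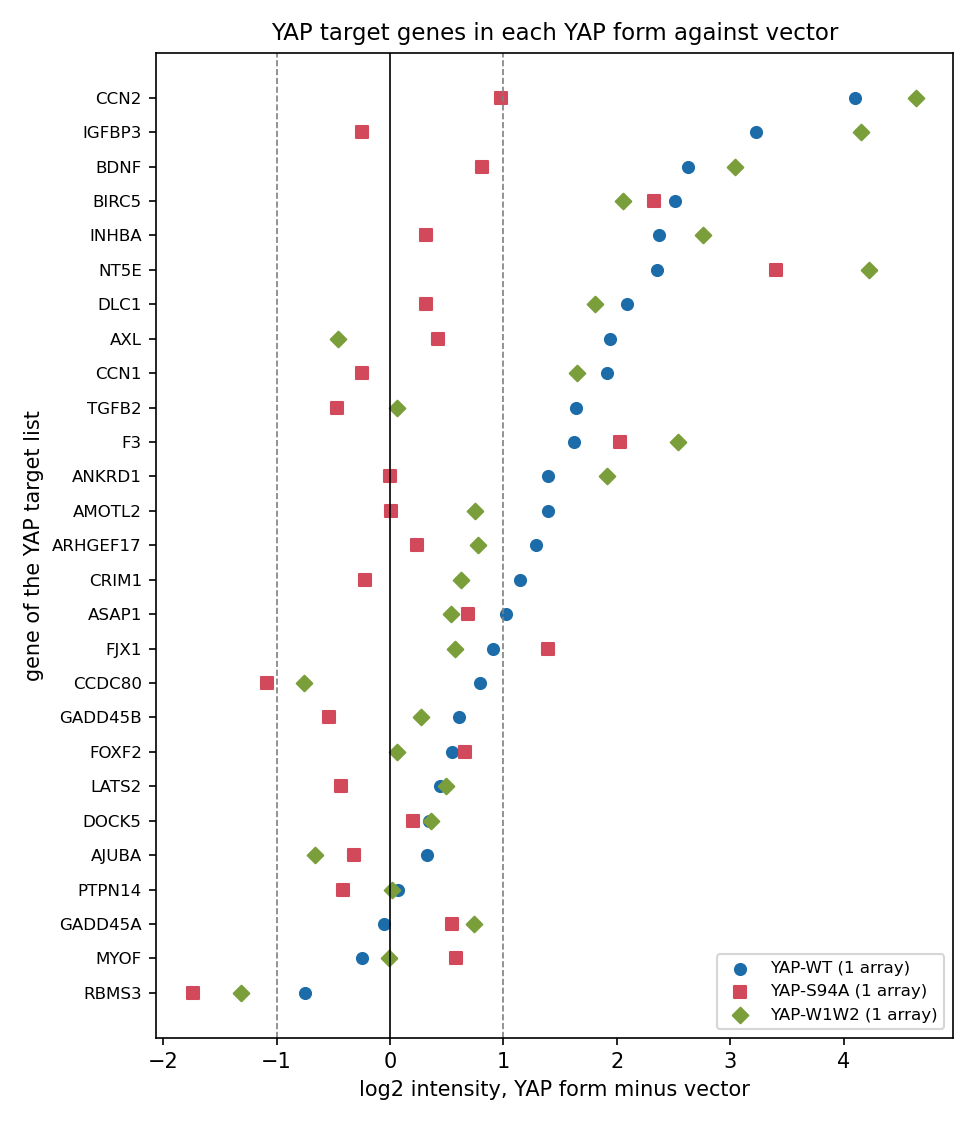
Log2 intensity of each measured gene of the YAP target list in YAP-WT, YAP-S94A and YAP-W1W2 minus that in vector, 1 array each, ordered by YAP-WT; dashed lines mark 2-fold. CCN2 lies at 4.10 in YAP-WT, 0.98 in YAP-S94A and 4.64 in YAP-W1W2, and BIRC5 lies above 2-fold in each.

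Comparing YAP-S94A directly with YAP-WT asks which transcripts differ with the TEAD-binding change and does not use the vector array. YAP targets, extracellular matrix and mesenchymal genes were lower in YAP-S94A, and epithelial junction, keratinocyte and cytokine genes were higher. Of 27 YAP targets 14 were at least 2-fold lower and 1, NT5E, higher, with a median log2 difference of −1.06, below all random lists. IGFBP3 was 11.2-fold lower, CCN2 8.68-fold, CCN1 4.48-fold, INHBA 4.15-fold and AXL 2.88-fold. TGFB2 was 4.34-fold lower by its brightest probe set, and another went the other way. Of 32 extracellular matrix genes 19 were lower and 2 higher (median −1.22), with COL12A1 10.3-fold and fibrillin FBN1 9.06-fold lower. Of 20 mesenchymal genes 11 were lower and 1 higher (median −1.13), with the lysyl oxidase LOX 7.92-fold and fibronectin FN1 5.41-fold lower. The mesenchymal list shares genes with the extracellular matrix list, FN1 and SPARC among them. Of 10 fibroblast genes 7 were lower and 1 higher, with a median of −1.41, below all random lists; without the filter on dim genes this median was 0.00. In contrast, 11 of 24 epithelial junction genes were higher and 0 lower (median 0.87), among them CLDN4 at least 15.5-fold and ESRP1 5.31-fold. Keratinocyte differentiation genes had a median of 0.88, with 13 of 28 higher and 2 lower. Cytokine genes had a median of 1.03, with 10 of 20 higher and 1 lower, and this median was 0.14 without the filter on dim genes.

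The single genes highest in YAP-S94A relative to YAP-WT were CXCL8 (28.5-fold), ANGPTL4 (18.8-fold), the cornified envelope gene SPRR2B (13.5-fold), the calcium-binding S100P (10.5-fold), KRT15 (10.3-fold), XDH (10.2-fold), MACC1 (8.89-fold) and CXCL2 (8.18-fold). The lowest were the proteoglycan SRGN (46.3-fold lower), the lipid kinase PIK3C2B (42.3-fold), WNT5A (28.6-fold), the transporter ABCA8 (18.8-fold), KRT4 (18.6-fold), the endocytic adaptor DAB2 (15.1-fold), DCN (13.5-fold) and CYBRD1 (12.6-fold). Both rankings cover only genes above the floor on both arrays. PIK3C2B rested on 1 probe set at 74.0 in YAP-S94A, just above the floor, so its fold is close to a bound. KCNT2, below the floor in YAP-S94A, was lower than SRGN, at a log2 difference of −5.9 or lower. In total 646 genes were at least 2-fold higher and 800 lower, 11.3% of those measured. The simulated share was 11.32%, but its noise was the whole difference between the YAP-WT and YAP-W1W2 arrays. It therefore does not show how many of these genes are noise. The mitosis list differed little, with 0 of 35 genes changed 2-fold and a median of 0.11. The DNA replication list had a median of 0.54, with 3 of 31 higher.

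Comparing YAP-W1W2 with YAP-WT asks the same of the WW domains. Here 499 genes were at least 2-fold higher and 713 lower, so 41.2% were higher. Together they were 9.5% of those measured. The simulated share of 11.32% took its noise from the whole difference of this same pair, so it cannot tell changed genes from noise here. After median centring the counts were 680 and 505, with 57.4% higher, and the median gene then stood at 0.09. The keratin KRT13 was 12.6-fold higher, the integrin subunit ITGA2 9.51-fold, CST6 8.82-fold, the retinaldehyde dehydrogenase ALDH1A3 8.50-fold, ANHX 7.69-fold, STXBP6 6.91-fold and ADAMTS10 6.83-fold. ZNF710 was 7.70-fold higher by its brightest probe set, and another went the other way. ALPP was 17.5-fold lower, DCN 15.6-fold, ZBTB40 10.7-fold, KCNT2 9.92-fold, CLCA2 9.21-fold, CYP1B1 8.83-fold and S100A8 8.64-fold. PNPLA4 was 10.5-fold lower by 1 probe set, with another going the other way. Another probe set gave only 0.83 (log2) for STXBP6 and −0.27 for ZBTB40. ADAMTS10 rested on 1 probe set, with an intensity of 75.9 in YAP-WT, near the floor. Among YAP targets 3 of 27 were at least 2-fold lower and 1 higher, with a median log2 difference of −0.27, above 66 of 10000 random lists; AXL was 5.31-fold lower and NT5E 3.65-fold higher. Cholesterol synthesis genes were lower, with 5 of 18 at least 2-fold and a median of −0.66, below all random lists, among them TM7SF2 (4.85-fold) and MVD (3.81-fold). Extracellular matrix genes had a median of −0.32, and epithelial junction genes 0.41, with 7 of 24 higher.

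The study's mutants ask how much of the YAP-WT profile each mutant keeps. Of the 1162 genes at least 2-fold higher in YAP-WT than in vector, 598 were at least 2-fold higher in YAP-S94A too (51.5%, Wilson 95% interval 48.6 to 54.3) and 794 in YAP-W1W2 (68.3%, 65.6 to 70.9). The log2 change was under 0.5 for 320 of them in YAP-S94A and for 142 in YAP-W1W2. Independent lists of these sizes would share 119 and 133 genes. All comparisons with vector use the same vector array, whose own deviation is part of each overlap, and the difference between the 2 shares was not tested. Genes picked on YAP-S94A were at least 2-fold higher in YAP-WT in 45.6% of 1312 cases, and in YAP-W1W2 in 60.4%. Genes picked on YAP-W1W2 were higher in YAP-WT in 54.4% of 1460 cases, and in YAP-S94A in 54.2%. Of the 631 genes lower in YAP-WT, 262 (41.5%) were lower in YAP-S94A and 356 (56.4%) in YAP-W1W2. Lower genes picked on YAP-S94A were lower in YAP-WT in 31.5% of 833 cases and in YAP-W1W2 in 57.4%. Those picked on YAP-W1W2 were lower in YAP-WT in 33.2% of 1072 cases and in YAP-S94A in 44.6%. By this exchange the mutants shared as many or more of their changes with each other as with YAP-WT.

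The gene lists divided in what was kept. Of 56 DNA replication and mitosis genes higher in YAP-WT, all 56 were at least 2-fold higher in YAP-S94A and 52 in YAP-W1W2, and 0 had a log2 change under 0.5. Of 16 YAP targets higher in YAP-WT, 3 were retained and 10 lost in YAP-S94A, against 10 retained and 2 lost in YAP-W1W2. The 3 were NT5E, F3 and BIRC5, which also stands in the mitosis list. AXL and TGFB2 were the 2 lost in YAP-W1W2. Of 17 higher extracellular matrix genes, 2 were retained, 7 lost and 8 between in YAP-S94A, against 14, 2 and 1 in YAP-W1W2. Of 12 lower cytokine genes, 2 were retained and 8 lost in YAP-S94A, against 10 and 1 in YAP-W1W2.

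**Figure D3:**
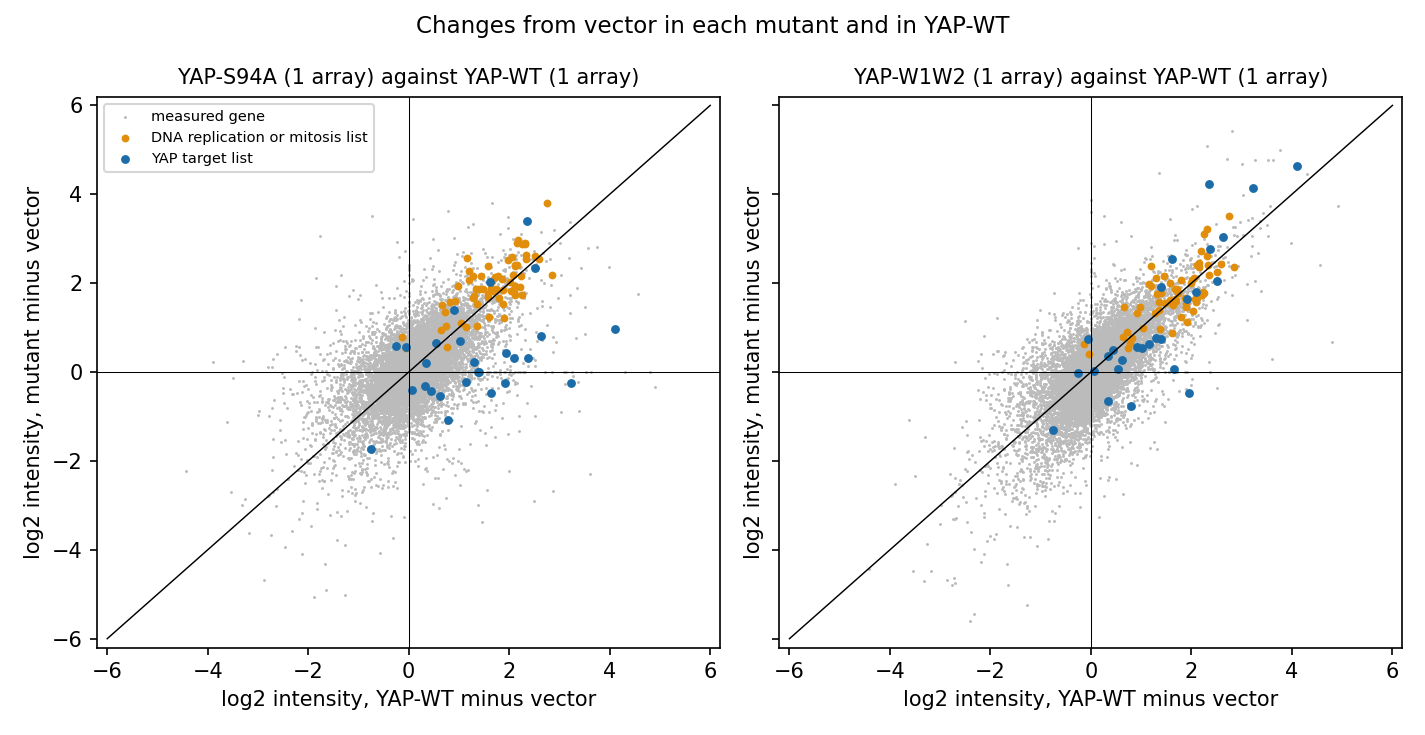
Each point is 1 of 12759 measured genes; the horizontal axis is log2 intensity in YAP-WT minus vector and the vertical axis that of YAP-S94A (left) or YAP-W1W2 (right) minus vector, with the line of equal change. In YAP-S94A, DNA replication genes lie above the line by a median of 0.54 and mitosis genes by 0.11, and the YAP target median is 0.24 against 1.29 in YAP-WT.

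Across genes, YAP-WT minus vector correlated with YAP-W1W2 minus YAP-S94A, a pair of differences that shares no array, with Pearson's r of 0.29 and Spearman's rho of 0.20. The other ways to pair the arrays gave r of −0.05 for YAP-WT minus YAP-S94A with YAP-W1W2 minus vector, and −0.34 for YAP-WT minus YAP-W1W2 with YAP-S94A minus vector. With the vector array shared, r was 0.58 for YAP-WT with YAP-S94A, 0.73 for YAP-WT with YAP-W1W2 and 0.71 for the mutants, where arrays simulated with no effect gave 0.50. The covariances were 0.326, 0.458 and 0.488, which exceeded the simulated ones by 0.144, 0.275 and 0.306. A vector array with a larger deviation of its own than was simulated would raise these correlations and covariances without any effect of YAP. The SD of the log2 difference was 0.7189 to 0.8779 between vector and the YAP arrays, against 0.6102 for YAP-WT with YAP-W1W2. The excess is therefore not evidence of a shared YAP effect. Of 5954 genes with a second measured probe set, that probe set went the same way for 88.0% of the genes at least 2-fold higher in YAP-WT than in vector and passed 2-fold for 48.7%. Agreement was weaker in YAP-W1W2 against YAP-WT. There the second probe set went the same way for 77.6% of higher and 83.6% of lower genes, and passed 2-fold for 35.8% and 36.0%.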

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

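The tests of explanations below were chosen after the results were seen, except the test on FOXO target genes, whose bound was written before its values were computed but after related genes, PDK4 and KLHL24 among them, had been seen to be lower than in vector. Some genes were at least 2-fold from vector in opposite directions in YAP-WT and a mutant; each rests on 1 array per group, and the differences were not tested. In YAP-S94A minus YAP-WT the log2 differences were −5.53 for SRGN, −5.40 for PIK3C2B, −4.84 for WNT5A, −4.23 for ABCA8, −4.22 for KRT4 and, as a bound because YAP-S94A lay below the floor, −5.90 or lower for KCNT2, all higher than vector in YAP-WT and lower in YAP-S94A. The reverse held for CXCL8 (4.83), SPRR2B (3.76), S100P (3.39) and ALDH1A3 (2.87). PIK3C2B lay just above the floor in YAP-S94A, at 74.0, so its difference is close to a bound. In YAP-W1W2 minus YAP-WT the differences were 3.65 for KRT13, 3.09 for ALDH1A3 and −2.58 for WNT5A. Over all measured genes, 24 were higher in YAP-WT and lower in YAP-S94A and 15 the reverse, against 6 and 5 for YAP-W1W2. The actin control probe sets, which enter no comparison, were higher than in vector by 0.68 (log2) in YAP-S94A and 0.80 in YAP-W1W2.

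DNA replication and mitosis genes were higher in each YAP array than in vector, with medians of the 66 genes together of 1.72, 1.90 and 1.74 (log2) in YAP-WT, YAP-S94A and YAP-W1W2. Scaling or a trend with intensity is argued against, since the lowest median over 3 scalings and 3 comparisons was 1.54. The YAP forms differed from each other in these genes by a median of at most 0.28 over the 66, and the lower mutant median was 1.74; DNA replication genes alone were higher than in YAP-WT by 0.54 in YAP-S94A and 0.29 in YAP-W1W2. A deviation of the single vector culture or array therefore cannot be told apart from an effect of any YAP form that needs neither TEAD binding nor the WW domains, since all 3 comparisons use that 1 vector array. FOXO targets and quiescence genes, whose values had not been looked at, were lower in each YAP array (highest percentile among random lists 0.0). This met the bound written for a lower state of growth stimulation in the vector cells, whatever set it. The list was chosen after related genes were seen to be lower, and the 3 comparisons share the vector array, so it is not separate support. The list was also lower in YAP-S94A (median −0.59) and YAP-W1W2 (−0.48) than in YAP-WT, which a state of the vector cells alone does not cover.

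YAP target and extracellular matrix genes, 57 together, were lower in YAP-S94A than in YAP-WT with a median of −1.17 (log2). Scaling is argued against, since the highest median over 3 scalings was −1.15. A deviation of the YAP-WT array as the whole of this difference is argued against as well. In YAP-W1W2 minus YAP-S94A, which leaves that array out, the median of the same genes was 0.53, above all 10000 random lists. This is smaller in size than −1.17, and YAP-W1W2 lay below YAP-WT by a median of −0.34. A part coming from the YAP-WT array therefore stays open. A lower amount of YAP-S94A than YAP-WT in the cells cannot be told apart from a loss of TEAD binding, because no YAP1 probe set was higher in YAP-WT than in vector by more than 0.13 and whether these probe sets lie within the constructs is not known. All 3 read higher in YAP-S94A than in YAP-WT (intensities of 1552.2 against 871.8, 4284.6 against 3908.4 and 4208.4 against 3461.5), which is the opposite direction to a lower amount but may be the cells' own YAP1. A deviation of the single YAP-S94A array was not tested and stays open, as does the biological difference between the forms.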

How the results depend on the processing

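The alternatives for the FOXO and quiescence list were added after the data had been seen. Of 129 values that 13 counts, shares and correlations took under the alternatives, 97 stayed within 1.5 times the count, within the interval of the share or close to the correlation, and 32 moved. Of 1620 values that 180 list medians took under the alternatives, 1585 stayed within 1.5-fold and 32 moved. The other 3, of medians outside the central 95% of random lists, took the other sign. Counted over all medians, 74 values of 39 medians took the other sign, 40 of them under the 3 rescalings; apart from those 3, the medians were at most 0.44 in size. Of 1934 values of the genes named, 1861 stayed within 1.5-fold, 72 moved and 1 took the other sign. No paired analysis was possible because each group had 1 array.

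With the filter at the 70th percentile fewer genes were counted, as that filter removes genes by construction: 731 higher and 260 lower for YAP-WT against vector, 853 and 446 for YAP-S94A, 890 and 629 for YAP-W1W2, 296 and 459 for YAP-S94A against YAP-WT, and 148 and 383 for YAP-W1W2 against YAP-WT. The 3-fold threshold lowered the same counts by construction, to 406 and 203, 423 and 296, 511 and 431, 175 and 290, and 126 and 172 in that order.

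Of genes higher in YAP-WT, the share also higher in YAP-S94A was 56.9% with the floor at the 20th percentile, 54.9% with no floor, 47.1% with no filter, 54.6% with the filter at the 70th percentile and 46.3% at 3-fold. The share in YAP-W1W2 was 73.8% after median centring, 71.7% after quantile normalization, 72.3% with the lower floor, 71.1% with no floor, 63.1% with no filter, 72.5% with the stricter filter and 59.6% at 3-fold. The cause of these moves was not tested. Under each alternative the share was larger in YAP-W1W2 than in YAP-S94A.

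With the mean over probe sets the extracellular matrix median in YAP-S94A against vector was 0.01. With the filter at the 70th percentile the Notch median in YAP-WT was 0.13. With probe sets lacking the _s_at or _x_at suffix only, the stem-like median in YAP-W1W2 against YAP-S94A was 0.11 and GINS2 in YAP-WT was −0.37. The cause of these and the other changes of sign was not tested. Among the moved medians were those of lists with few measured genes, such as EGF ligands, fibroblast, immune and endothelial genes, and the cytokine list without the filter.

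Signal over background limits these values: 200 of the 1162 genes higher in YAP-WT had a vector value at the floor, so their folds are bounds. In simulated arrays 11.32% of unchanged genes passed 2-fold. The shares were 14.1% of genes in YAP-WT against vector, 11.3% in YAP-S94A against YAP-WT and 9.5% in YAP-W1W2 against YAP-WT. The simulated noise came from the YAP-WT and YAP-W1W2 arrays, the most alike pair (SD of log2 difference 0.6102, against 0.7189 for YAP-WT with vector). It is an upper value for that pair only and need not bound the noise of the vector or YAP-S94A array. The gene counts therefore carry an unknown share of noise. The list medians do not rest on single genes, but a deviation of 1 array or culture can move a whole list, and some medians depended on the filter.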

Other observations

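The lists not described in the report against vector, and the full values of some that were, are given here. The medians of 10 of them lay inside the central 95% of random lists in all 3 YAP forms: mesenchymal genes, Hippo components, the TGF-beta and BMP pathway, apoptosis regulators, basal mammary genes, ribosomal proteins, hypoxia and glycolysis, the unfolded protein and amino acid response, and immune and endothelial genes. So did the medians of epithelial junction genes in both mutants, of EGF ligands and fibroblast genes in YAP-WT, of Wnt, Notch and respiratory chain genes in YAP-S94A, of interferon and stem-like genes in both mutants, and of fibroblast and cholesterol synthesis genes in YAP-W1W2. Immediate early genes, which respond to growth factor and ERK signalling, had medians of 0.57, 1.07 and 0.73 (log2) over vector in YAP-WT, YAP-S94A and YAP-W1W2, with 4, 11 and 9 of 21 at least 2-fold higher. DUSP6 was 3.94-fold, 11.1-fold and 5.71-fold higher in that order. EGF family ligands had medians of 0.20, 1.49 and 1.09 over 5 genes. Actin cytoskeleton and SRF genes had medians of 0.68, 0.59 and 0.78 over 24 genes, with TAGLN, the smooth muscle protein transgelin, 3.89-fold, 5.78-fold and 5.81-fold higher. Luminal mammary genes had medians of 0.72, 0.80 and 0.89 over 14 genes, led by the keratin KRT18 at 3.03-fold, 3.23-fold and 6.17-fold; without the filter on dim genes the YAP-S94A median was 0.00. Cholesterol synthesis genes stood at 0.84, 0.52 and −0.08. Among 23 Hippo pathway components the median was 0.30 in YAP-WT, and TEAD4 was 3.40-fold, 3.80-fold and 5.36-fold higher; in YAP-S94A (0.01) and YAP-W1W2 (0.02) the median was below 0 after each rescaling. Wnt pathway genes had medians of 0.64, 0.14 and 0.49, the YAP-S94A value being −0.01 after median centring, −0.03 with the mean over probe sets, −0.35 with probe sets lacking the _s_at or _x_at suffix only and −0.37 with the filter at the 70th percentile. Epithelial junction genes, at −0.39 in YAP-WT, had medians of 0.44 in YAP-S94A, with 3 of 24 at least 2-fold higher and 1 lower, and 0.19 in YAP-W1W2, with 3 higher and 4 lower. Mesenchymal genes had medians of 0.30, −0.05 (0.12 without suffixed probe sets) and 0.34.

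On the lower side, Notch pathway genes had medians of −0.48, −0.12 and −0.75 over 12 genes, with the Notch target HES1 3.26-fold lower in YAP-WT and 3.63-fold lower in YAP-W1W2; with the filter at the 70th percentile the YAP-WT median was 0.13. Interferon response genes had medians of −0.42, −0.07 and −0.12 over 29 genes, with IFI27 5.17-fold lower in YAP-WT. The medians of p53 targets were −0.26, −0.27 and −0.46 over 22 genes, with TP53INP1 2.11-fold, 6.79-fold and 5.87-fold lower. Mitochondrial respiratory chain genes stood at −0.09, 0.01 and −0.23, with 0 of 26 changed 2-fold; the YAP-S94A value was below 0 after each rescaling and under both other choices of probe set. Cytosolic ribosomal protein genes stood at 0.04, 0.19 and 0.13, with 0 of 29 changed 2-fold, and took the other sign in each form after quantile or cyclic loess normalization, and in YAP-WT after median centring too. Basal mammary genes stood at 0.16, −0.09 and −0.17, the first being −0.05 after cyclic loess normalization and the second 0.02 with the mean over probe sets, and stem-like genes, of which 6 were measured, at −0.48, 0.27 and −0.30, the second being 0 after cyclic loess normalization. The medians were 0.33, 0.32 and 0.41 for the unfolded protein and amino acid response, 0.03, 0.14 and 0.28 for the TGF-beta and BMP pathway, 0.09, 0.29 and 0.16 for hypoxia and glycolysis, and 0.01, 0.19 and −0.17 for apoptosis regulators. The last 3 lists changed sign under some alternatives. In YAP-WT their values were below 0 after each rescaling, and also below 0 for the TGF-beta list with the mean over probe sets and for apoptosis regulators without suffixed probe sets. Without those probe sets the YAP-S94A value was −0.06 for hypoxia and −0.05 for apoptosis, and with the mean over probe sets the YAP-W1W2 value for apoptosis was 0.01. The YAP-S94A value of the TGF-beta list was −0.01 after median centring, and the YAP-W1W2 value of the hypoxia list was −0.04 after quantile and −0.06 after cyclic loess normalization. Of markers of other cell types, 10 of 15 fibroblast, 5 of 20 immune and 3 of 13 endothelial genes were measured. Fibroblast genes had medians of 0.24, −0.76 and 0.16, but the direction in YAP-WT and YAP-W1W2 is not settled: these 2 medians were −0.13 and −0.36 with the mean over probe sets and −0.49 and −1.05 without suffixed probe sets, and the YAP-W1W2 median was −0.21 with the filter at the 70th percentile. Immune genes had medians of 0.10 (−0.06 after median centring), −0.07 and −0.45, and endothelial genes 0.53, 0.22 and 0.91. DCN, in the fibroblast list, had an intensity of 9343.9 in vector, 3884.2 in YAP-WT, 288.0 in YAP-S94A and 248.3 in YAP-W1W2.

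A further list was written after part of the data had been seen, when PDK4, FBXO32, KLHL24, PNRC1, SELENOP and TP53INP1, several of them known FOXO targets, had been seen to be lower than in vector. It was the 1 list made in this way. It held 27 other FOXO targets and quiescence genes whose values had not been looked at, and the bound for the test was set before they were computed. The genes were lower than in vector by a median of −0.72 (log2) in YAP-WT, −1.45 in YAP-S94A and −1.21 in YAP-W1W2, with 9, 18 and 17 at least 2-fold lower and 0 higher; each median was below all 10000 random lists, so the highest percentile was 0.0. The cyclin CCNG2 stood at −1.20, −1.61 and −1.68, with probe sets in both directions in YAP-W1W2, the PI3-kinase subunit gene PIK3R1 at −1.19, −1.95 and −2.39, and CREBRF at −1.35, −3.23 and −2.63. Against YAP-WT, the list median was −0.59 in YAP-S94A and −0.48 in YAP-W1W2, both below all 10000 random lists. In YAP-W1W2 against YAP-S94A it was 0.25, above 9992 of them. As a hypothesis, the vector cells may have been harvested in a less growth-stimulated state than the YAP cells. Chosen in this way, the list is not separate support for it. A state of the vector cells alone does not cover the differences between the YAP forms. TSC22D3 (−0.84, −3.03 and −3.36) and KLF9 (−1.55, −2.43 and −2.82, with probe sets in both directions) also respond to hydrocortisone, a component of the medium, so a difference in that response is not excluded. The genes of this list that are named were chosen after their values were seen. Whether the state came from YAP or from the culture, such as its density, is open with 1 vector array.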
